A study of Mus musculus with 6 samples.

How the data were processed

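Polyadenylated RNA of isolated mouse islets was sequenced in 3 control and 3 prolactin libraries, made with a NEBNext Ultra II kit and run on an Illumina NovaSeq X Plus, per the labels' protocols. The deposited counts are whole numbers of reads per gene, made with featureCounts 2.0.3 and GENCODE vM10 gene models grouped by gene name, per the file headers. The submitters' processing notes name the mm10 build, SAMtools 1.21, Subread 2.1.0 (the package that holds featureCounts, so its version there differs from the headers') and DESeq2. The aligner is not given in the sources used here. The recorded command has no option for strand, so reads of overlapping genes on opposite strands were not told apart. It has the option for paired reads and none for counting pairs, and even counts were in surplus among low counts (53.9% to 56.3% of the counts from 1 to 20), so that both mates of a pair can be counted and the counts overstate the number of independent fragments. Genes that share a name were merged, and 8 names stand on several chromosomes. A second deposited table holds, per the file headers, the authors' log2 fold changes with standard errors, p-values and adjusted p-values, a test statistic, which is a score, and a mean signal per gene over the libraries. Running DESeq2 with its defaults on the 6 count tables gave the authors' deposited log2 fold changes within a tolerance of 1.0e-06 for all genes, a bound set after the differences were seen. Coordinates are those of the file headers' gene models on mm10. The gene types of GENCODE vM21 on the same assembly and the synonyms of a RefSeq table were used for names only; 3 of 728 list entries matched through a synonym and 0 were unmatched.

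From the counts, edgeR 4.0.16 in R 4.3.3 was run with TMM scaling and its expression filter (minimum count 10, minimum total 15), which kept 23924 of 48397 genes. A quasi-likelihood fit with the condition as its only term gave a two-sided test of prolactin against control, with Benjamini-Hochberg adjustment and a threshold of 0.05. CPM use the TMM-scaled totals. The SE of a log2 change was taken from the test statistic. At a mean of 5 CPM or more its median was 0.0672, while genes under 1 CPM rest on fewer reads. The counts per library ranged from 230833584 to 530296257. Because mates may have been counted separately, no interval from counts alone is given.

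Before the data were examined, the design, 30 gene lists, the alternatives and the rule for naming genes were fixed. The rule took 21 genes of the study's topic, up to 10 largest rises and 10 largest falls among changed genes with a name, a mean of at least 5 CPM and separated libraries, up to 4 members per list with the smallest p-values, and the 5 most abundant genes. It gave 140 genes and passed over 6 loci without a gene name; some of these genes are not reported here. Genes named outside it were chosen after their values were seen. Lists were tested with camera of limma 3.58.1 on the edgeR fit, with a preset inter-gene correlation of 0.01, and with the correlation estimated from the data; the adjustment is over the 30 lists. The self-contained test fry asks whether a list's genes move one way on balance and does not compare them with other genes. A list is said to be called when its adjusted p lies under 0.05.

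Alternatives fixed beforehand were DESeq2 size factors, upper-quartile scaling, no filter, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, leaving out each library, leaving out hormone and mitochondrial genes, and a test against a change of 1.2-fold. Summing prolactin replicates 2 and 3, halving the counts and the other setting of edgeR's legacy option were added after the data were seen.

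The procedure was tested on simulated data, with counts drawn for the 23924 genes of the prolactin and control comparison and 250 genes per size of change over 5 simulations. The edgeR test recovered 38.8% of genes changed by 0.5 on the log2 scale, 66.8% at 1, 93.2% at 2 and 96.0% at 3. False calls made up 10.1% of the edgeR calls, 22.9% of those of DESeq2 and 9.07% of those of limma-voom, all above the nominal 5%. Camera called 10 of 10 shifted lists and 0 of 40 unshifted ones. The simulated genes were drawn independently, so this does not test lists whose genes move together. The stromal list, for example, had an estimated correlation of 0.741. All columns with values per sample were used.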

Results

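Gene expression was measured by sequencing polyadenylated RNA from isolated pancreatic islets of wild-type C57B6 mice, which hold insulin-producing beta cells together with other endocrine and non-endocrine cells. The islets were cultured for 24 h with DMSO, the solvent control, or with 500 ng/mL of recombinant mouse prolactin, a pituitary hormone that acts on beta cells in pregnancy. Each condition had 3 libraries. Read counts assigned to genes were 530296257, 281202173 and 264466143 in control replicates 1, 2 and 3, and 231247908, 230833584 and 264885071 in prolactin replicates 1, 2 and 3. Values are CPM, read counts scaled to a common library size, as mean ± SD over the 3 libraries of a condition, and changes are log2 ratios of prolactin over control with their standard error (SE). The labels do not say whether replicates came from separate animals or cultures, so the p-values measure only the spread between these samples, which may be technical.

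The comparison asks which transcripts differ in islets after a day of prolactin, in a study of signalling from the prolactin receptor, chromatin in beta cells and the transcription factor OVOL2. More genes were higher than lower in prolactin. Transcripts of the STAT5 feedback inhibitors Cish and Socs2, of the prolactin receptor Prlr itself, of the serotonin-synthesis enzyme Tph1 and of Ovol2 rose, and the transcriptional repressor Bcl6 fell. Among 23924 genes tested, 156 were higher and 25 lower in prolactin at an adjusted p under 0.05 in edgeR's quasi-likelihood test. Of these, 38 rose at least 2-fold and 0 fell at least 2-fold (60 fell that far at an unadjusted p under 0.05, 3 by DESeq2 and 0 by limma-voom), with a median of 1.56-fold for the higher genes and 0.74-fold for the lower ones. In all 181 changed genes the 3 prolactin libraries lay on one side of the 3 control libraries. That held for 5178 of the tested genes (21.6%), where chance gives 10% if the 6 libraries are independent. Prolactin replicates 2 and 3 were much closer than other replicate pairs, so the chance share may be higher.

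The 10 largest rises among named genes with a mean of at least 5 CPM were in Cish, Stab2, Neb, Fmo1, Socs2, Enpp2, Gbp11, Trpm1, Prlr and Amigo2. Stab2, a scavenger receptor, went from 2.27 ± 0.19 to 8.82 ± 0.51 CPM (log2 change 1.96, SE 0.096, adjusted p = 5.5e-05). Neb, the sarcomere protein nebulin, went from 15.3 ± 1.6 to 49.2 ± 3.0 CPM (log2 change 1.69, SE 0.084, adjusted p = 5.5e-05). Enpp2, which encodes the lysophospholipase autotaxin, was already abundant and rose from 289.2 ± 15.0 to 669.6 ± 71.0 CPM (log2 change 1.21, SE 0.087, adjusted p = 0.00045). The flavin monooxygenase Fmo1 rose by 1.34 on the log2 scale, the cation channel gene Trpm1 by 1.11 and the adhesion gene Amigo2 by 1.04. The guanylate-binding protein gene Gbp11 rose by 1.19, although members of that family are close in sequence and reads may be divided between them. All 10 passed the edgeR test in each of the 6 fits that left out 1 library. Neb overlaps a locus without a gene name on the opposite strand, and counting without strand cannot part their reads.

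**Figure D1:**
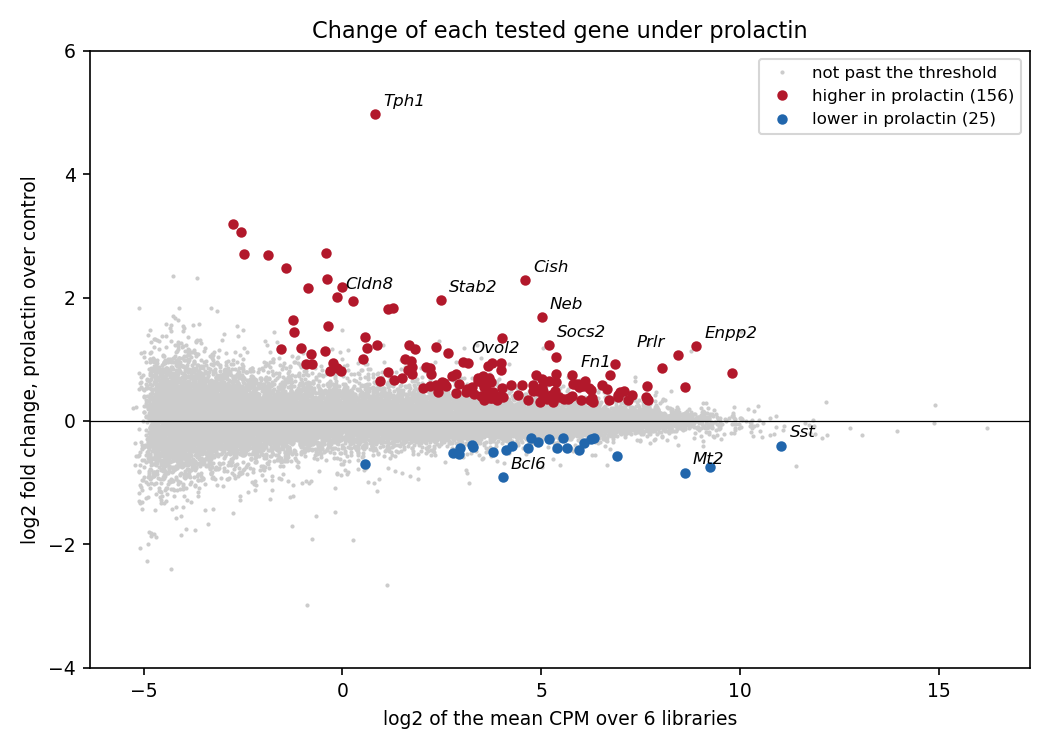
Log2 fold change of prolactin over control for each of the 23924 tested genes, against the log2 of its mean CPM over the 6 libraries; red points are the 156 genes higher and blue points the 25 genes lower in prolactin at an adjusted p under 0.05, and grey points did not pass. Most coloured points lie above 0, with Tph1 highest at 4.97 and Bcl6 lowest at -0.91.

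In the list of the prolactin receptor, the JAK2-STAT5 pathway and its feedback inhibitors, 3 of 17 tested members rose, 1 fell and 13 did not pass. Cish (chromosome 9, 107296026 to 107302784, mm10) went from 8.16 ± 0.58 to 39.8 ± 2.9 CPM, a log2 change of 2.28 (SE 0.078, edgeR adjusted p = 7.9e-06, n = 3 per condition). Socs2 (chromosome 10, 95385362 to 95417180) went from 21.9 ± 1.1 to 51.3 ± 3.9 CPM (log2 change 1.23, SE 0.070, adjusted p = 0.00012). Prlr (chromosome 15, 10177238 to 10349180) went from 226.0 ± 11.8 to 472.5 ± 28.5 CPM (log2 change 1.06, SE 0.069, adjusted p = 3.0e-04). Bcl6 (chromosome 16, 23965052 to 23988852), a repressor whose gene STAT5 is known to bind, was the largest fall, from 21.4 ± 1.9 to 11.4 ± 0.4 CPM (log2 change -0.91, SE 0.074, adjusted p = 0.00079). All 4 passed in each fit that left out 1 library. Transcripts of the pathway's kinase and transcription factors did not pass: Jak2 had a log2 change of -0.11, Stat5a -0.07 and Stat5b 0.08. Adjusted over the list alone, 3 members rose and 2 fell. The list was called up against the other genes by camera with a preset correlation (adjusted p = 1.0e-08), and not with an estimated correlation (adjusted p = 0.236). Its median log2 change was 0.04 (0.02 without control replicate 2) and its mean 0.21, with 11 of 17 changes positive. Cish overlaps the locus Gm17040 on the opposite strand, whose reads cannot be told from its own.

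**Figure D2:**
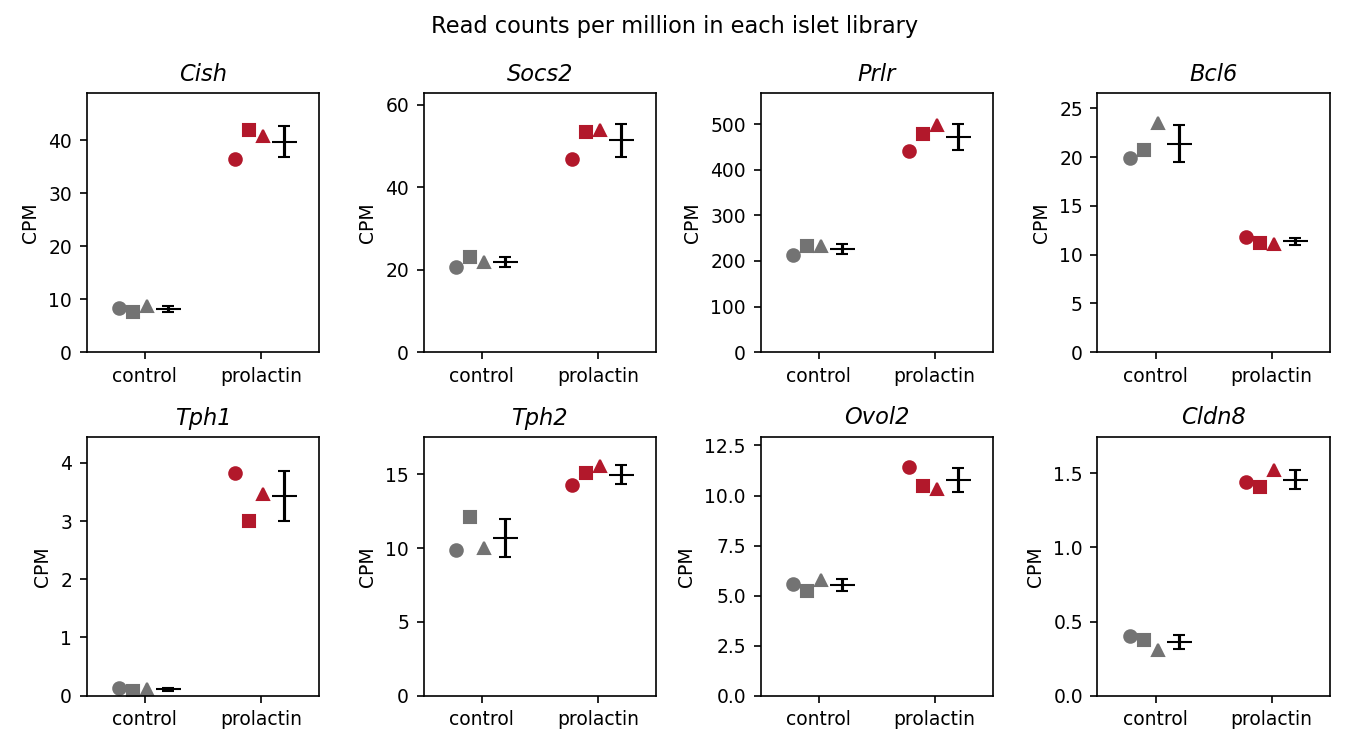
CPM of 8 genes in each library, with control in grey and prolactin in red; circles, squares and triangles are replicates 1, 2 and 3, and black bars are the mean ± SD of 3 libraries. In all 8 genes the 3 prolactin libraries lie on one side of the 3 control libraries, lower for Bcl6 and higher for the others, of which Tph2 did not pass the test (adjusted p = 0.0501).

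Genes known to change in mouse islets in pregnancy or under lactogens formed the list with the smallest camera p, and 5 of 19 tested members rose and 14 did not pass. Its median log2 change was 0.19, from 0.14 to 0.29 over the fits without 1 library, and lower than those of the stromal (0.52) and mesenchymal-state (0.41) lists. Tph1 (chromosome 7, 46644641 to 46672537), the rate-limiting enzyme of serotonin synthesis outside the brain, went from 0.107 ± 0.027 to 3.43 ± 0.42 CPM, 31.3-fold (log2 change 4.97, SE 0.20, edgeR adjusted p = 2.0e-05). The tight-junction gene Cldn8 went from 0.362 ± 0.047 to 1.46 ± 0.06 CPM (log2 change 2.00, adjusted p = 0.00056), and Gbp8 had a log2 change of 0.94 (adjusted p = 0.012). Tph1, Cldn8 and Gbp8 passed without each single library. Tnfrsf11b, which encodes the decoy receptor osteoprotegerin, had a log2 change of 0.73 (adjusted p = 0.033), and did not pass without control replicate 1 or 2 or prolactin replicate 2 or 3 (adjusted p from 0.0672 to 0.0967). 8 members rose and 1 fell when adjusted over the list alone. This list was the only one of 30 that camera called both with the preset correlation (adjusted p = 8.1e-20) and with an estimated correlation (adjusted p = 0.0206), and 15 of its 19 members also stand in another list.

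In the list of serotonin synthesis, storage, transport, breakdown and receptors, Tph1 was the 1 member of 17 that rose. Tph2, the neuronal isoform of the enzyme, went from 10.7 ± 1.3 to 15.0 ± 0.6 CPM, just short of the threshold (log2 change 0.49, SE 0.089, edgeR adjusted p = 0.0501), but it passed in 11 of the 17 alternative fits, among them limma-voom (adjusted p = 0.0452), DESeq2 (adjusted p = 4.5e-05) and the fit without control replicate 2 (adjusted p = 0.0243). The serotonin receptor genes Htr1b and Htr7 had log2 changes of 0.48 (adjusted p = 0.304) and 0.85 (adjusted p = 0.275) at under 1 CPM. Adjusted over the list alone, 2 members rose. The list was called up by camera (adjusted p = 2.7e-06), and not with an estimated correlation (adjusted p = 0.238). Its median log2 change was 0.07 against a mean of 0.425, which includes Tph1 at 4.97, and 11 of 17 changes were positive. The median was 0.20 without control replicate 2, 0.13 without prolactin replicate 2 and 0.02 without prolactin replicate 3.

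Ovol2 (chromosome 2, 144305175 to 144332146), a zinc-finger repressor that holds epithelial cells in their state, went from 5.53 ± 0.28 to 10.8 ± 0.6 CPM (log2 change 0.96, SE 0.077, edgeR adjusted p = 0.00078), and passed without each single library. A locus without a gene name on the opposite strand overlaps it. Its relative Ovol1 was near 0.2 CPM in both conditions (0.210 ± 0.052 and 0.172 ± 0.048 CPM, adjusted p = 0.699). Ovol2 was the 1 member of 21 in the list of OVOL factors and epithelial genes that rose, and also the 1 that did when adjusted over the list alone. The epithelial genes St14, Rab25 and Ocln had log2 changes of 0.33, -0.18 and -0.21, none past the threshold, though St14 passed without control replicate 3 (adjusted p = 0.043). The list was not shifted (camera adjusted p = 0.128), and was called up without control replicate 3 (adjusted p = 0.0196). Zeb1 and Zeb2, mesenchymal transcription factors, had log2 changes of 0.07 (adjusted p = 0.623) and 0.25 (adjusted p = 0.415). Among 49 tested chromatin regulators, 0 passed edgeR's test (2 higher and 1 lower at an unadjusted p under 0.05, 1 higher by DESeq2 and 0 by limma-voom). Dnmt3b had a log2 change of 0.39 (adjusted p = 0.136) and Kdm6b 0.23 (adjusted p = 0.268, and 0.0464 without control replicate 3). That list was not shifted (camera adjusted p = 0.29), but was called up without control replicate 3 (adjusted p = 0.00221) and without prolactin replicate 1 (adjusted p = 0.0192).

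Genes of the beta-cell programme did not pass: 0 of 37 tested members of the list of insulin, beta-cell transcription factors and secretion genes rose or fell in edgeR's test. At an unadjusted p under 0.05, 2 were higher and 2 lower, DESeq2 calls 2 higher, and limma-voom 0. The count was also 0 when adjusted over the list alone. Ins2 stood at 79029 ± 9802 CPM in control and 73423 ± 2423 CPM in prolactin (adjusted p = 0.751), and Ins1 at 30640 ± 4416 and 29956 ± 1536 CPM (adjusted p = 0.931); the sequences of this pair are close enough for reads to be shared. Iapp (log2 change -0.15, adjusted p = 0.447), Mafa (-0.18, adjusted p = 0.507) and the glucose transporter gene Slc2a2 (-0.30, adjusted p = 0.323) did not pass either. The largest change in the list was that of the channel gene Trpm5, 0.70 (adjusted p = 0.0826), which passed without prolactin replicate 1 (adjusted p = 0.0391). The list had a median log2 change of -0.01 (from -0.05 to 0.05 over the fits without 1 library), a mean of 0.01 and a camera direction of down (adjusted p = 0.875), so its signs differ.

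In the list of genes kept low in mature beta cells or raised in immaturity, 3 of 22 rose and 20 of 22 had positive changes, with a median log2 change of 0.27. They included the retinaldehyde dehydrogenase gene Aldh1a3 (log2 change 0.76, SE 0.11, edgeR adjusted p = 0.024) and the chemokine gene Cxcl12 (0.63, SE 0.077, adjusted p = 0.0097). Neither Aldh1a3 nor Cxcl12 passed without prolactin replicate 2 or without prolactin replicate 3, where adjusted p ranged from 0.0593 to 0.0774, and Aldh1a3 also failed without control replicate 1 (adjusted p = 0.0619) or 2 (adjusted p = 0.0863). Neurog3, an endocrine progenitor factor, had a log2 change of 0.49 (adjusted p = 0.0782). Adjusted over the list alone, 10 members rose. Camera called the list up (adjusted p = 2.6e-11), but not with an estimated correlation (adjusted p = 0.238). Its level was lowest in control replicate 3, 0.33 below its mean log2 CPM over the libraries, and highest in prolactin replicate 1, 0.26 above, and that of the stromal markers likewise, 0.68 below and 0.42 above. Of its 22 members 5 stand in another list, and it holds genes that mesenchymal cells are known to express, such as Pdgfra (log2 change 0.52, adjusted p = 0.368) and Pcolce (0.41, adjusted p = 0.106). Among 15 alpha-cell markers, 1 rose (4 adjusted over the list alone), and Irx1 (0.45, adjusted p = 0.0532) and Irx2 (0.34, adjusted p = 0.154) did not pass, though both did without control replicate 1 (adjusted p = 0.0209 and 0.0144) and Irx1 also without control replicate 3 (adjusted p = 0.049); glucagon Gcg stood at 28088 ± 6684 and 33793 ± 647 CPM (adjusted p = 0.491). The alpha-cell list was called up (adjusted p = 1.3e-05), not with an estimated correlation (adjusted p = 0.511). Its median log2 change of 0.24 became 0.05 without control replicate 3 and 0.39 without control replicate 1. Among 10 delta-cell and PP-cell markers, the hormone gene Sst fell, from 2401 ± 134 to 1821 ± 31 CPM (log2 change -0.40, SE 0.072, adjusted p = 0.0488), which control replicate 3 alone could be left out without losing (adjusted p from 0.067 to 0.279 in the other 5 fits). With upper-quartile scaling (adjusted p = 0.0515) or halved counts (adjusted p = 0.0507) it did not pass. Ppy had a log2 change of -0.74 (SE 0.15, adjusted p = 0.0708) and passed without prolactin replicate 1 (adjusted p = 0.00609). 1 delta-cell or PP-cell marker rose and 2 fell when adjusted over the list alone. That list had a median of 0.05 (0.08 without control replicate 1, and from 0.02 to 0.03 without control replicate 2 or 3 or prolactin replicate 1), a mean of -0.02 and a downward camera direction (adjusted p = 0.298), and was called down without prolactin replicate 1 (adjusted p = 0.00937).

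Of 21 tested fibroblast, stellate-cell and pericyte markers, 3 rose (Col1a1, Col1a2 and Fn1), 21 had positive changes and the median log2 change was 0.52. Fibronectin Fn1 went from 41.3 ± 3.3 to 69.1 ± 8.2 CPM (log2 change 0.74, SE 0.091, edgeR adjusted p = 0.0092) and passed without each single library. The collagen I genes Col1a1 and Col1a2 went from 186.5 ± 38.1 to 338.6 ± 39.5 CPM (adjusted p = 0.038) and from 80.6 ± 19.4 to 152.5 ± 18.3 CPM (adjusted p = 0.048). Col1a2 also did not pass under the filter of 1 CPM in 3 libraries (adjusted p = 0.052). Both lost the call when any single library other than control replicate 3 was left out, with adjusted p from 0.0542 to 0.158. Acta2 had a log2 change of 0.93 (SE 0.20, adjusted p = 0.0805), and passed without control replicate 1 (adjusted p = 0.0363) or 3 (adjusted p = 0.0366). Adjusted over the list alone, 10 members rose. Camera called the list up (adjusted p = 3.0e-18), not with an estimated correlation (adjusted p = 0.238), and fry did not call it (adjusted p = 0.135). Control replicate 3 stood apart from the other libraries here: the mean log2 CPM of the list lay 0.68 below its mean over the libraries, against 0.04 and 0.09 below in control replicates 1 and 2. Without that library the median change was 0.30 (camera adjusted p = 4.3e-13).

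The list of mesenchymal-state genes overlaps it, with 4 of its 22 members in another list. Fn1 was its 1 member that rose (11 adjusted over the list alone), 21 of 22 had positive changes, and the median log2 change of 0.41 became 0.26 without control replicate 3, where this list was also lowest. Camera called it up (adjusted p = 1.2e-12), not with an estimated correlation (adjusted p = 0.29). All 19 endothelial markers had positive changes, with a median of 0.16 (0.11 without control replicate 2). Vwf, the von Willebrand factor gene, was the 1 that passed (log2 change 0.59, SE 0.080, edgeR adjusted p = 0.016), though not without control replicate 2 or prolactin replicate 2 or 3 (adjusted p from 0.0722 to 0.129). There were 8 endothelial markers that rose adjusted over the list alone, and camera called the list up (adjusted p = 8.7e-08), but not with an estimated correlation (adjusted p = 0.238).

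Markers of acinar cells, which make digestive enzymes, differed between libraries of one condition: their mean log2 CPM lay 1.36 above its mean over the libraries in control replicate 3 and 1.28 below it in control replicate 2. Of 20 acinar markers, 0 passed edgeR's test over all genes (1 higher at an unadjusted p under 0.05 and 1 by DESeq2, 0 by limma-voom), 1 rose when adjusted over the list alone, and the median log2 change of -0.44 turned to 0.32 without control replicate 3 and lay between -0.95 and -0.24 in the other such fits. The acinar list was not called with all libraries (camera adjusted p = 0.29), was called down without control replicate 2 (adjusted p = 1.3e-08) or prolactin replicate 1 (adjusted p = 0.00165), and was called up without control replicate 3 (adjusted p = 0.0175). Of 13 ductal markers 0 passed edgeR's test (0 adjusted over the list alone, 2 higher at an unadjusted p under 0.05, 1 by DESeq2 and 0 by limma-voom), and Sox9 had a log2 change of 0.34 (adjusted p = 0.162). The ductal list was not called (adjusted p = 0.0963), but was without control replicate 1 (adjusted p = 0.0176), prolactin replicate 2 (adjusted p = 0.0108) or prolactin replicate 3 (adjusted p = 0.0161), and with these last summed (adjusted p = 0.0121). Without prolactin replicate 1 its direction turned to down (median log2 change -0.05, adjusted p = 0.979). Of 22 macrophage and leukocyte markers 0 passed edgeR's test (0 adjusted over the list alone, 1 lower at an unadjusted p under 0.05, 0 by DESeq2 or limma-voom), with a median log2 change of 0.01 (from -0.05 to 0.04 over the fits without 1 library), a mean of -0.04 and a camera direction of down (adjusted p = 0.718).

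**Figure D3:**
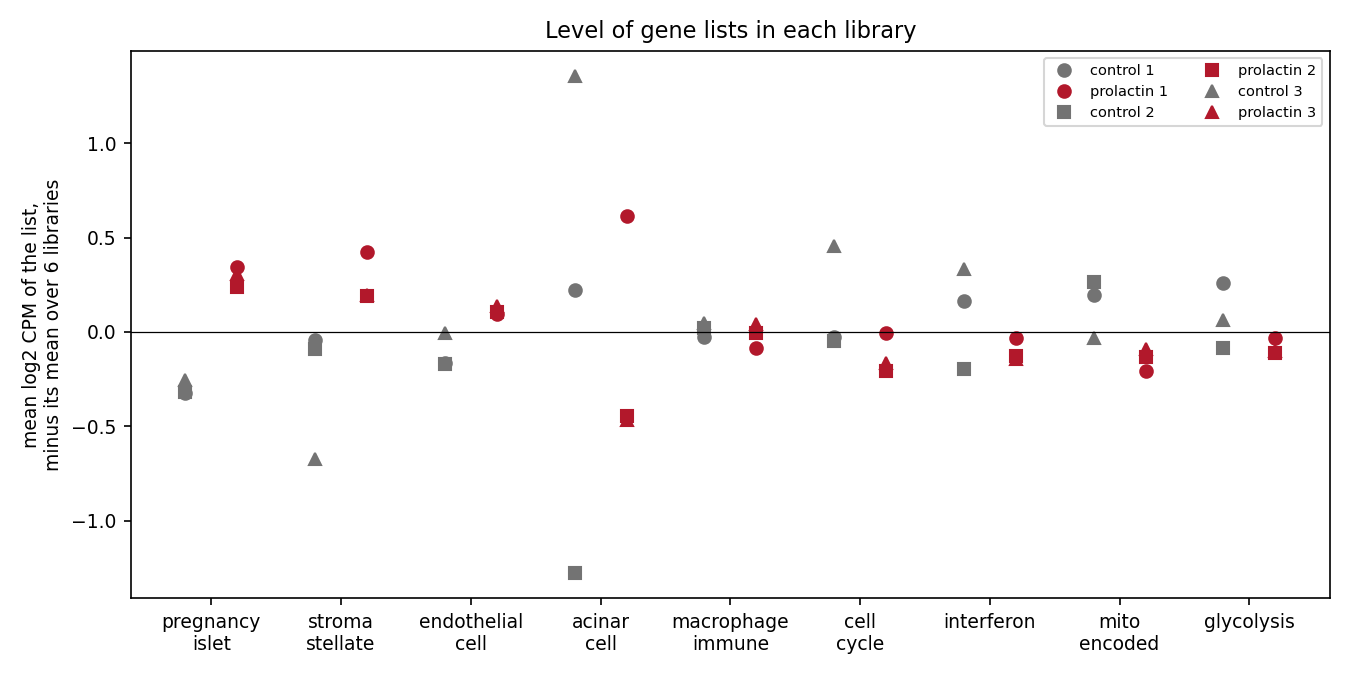
Mean log2 CPM of 9 gene lists in each library, minus the list's mean over the 6 libraries, with control in grey, prolactin in red and replicates 1, 2 and 3 as circles, squares and triangles. For the pregnancy list the prolactin libraries lie at 0.24 to 0.35 and the controls at -0.32 to -0.26, while for acinar markers the spread within control runs from -1.28 to 1.36.

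Among growth factor genes, 3 of 32 rose: the activin subunit gene Inhba (log2 change 0.75, SE 0.14, edgeR adjusted p = 0.0486), Tnfrsf11b, and Pdgfb (0.31, SE 0.049, adjusted p = 0.030). Of the fits without 1 library, Pdgfb passed in the one without control replicate 3 (adjusted p from 0.0643 to 0.215 in the others), and Inhba did not pass without control replicate 2 or any 1 prolactin library (adjusted p from 0.144 to 0.191), nor with limma-voom (adjusted p = 0.0514), upper-quartile scaling (adjusted p = 0.0506), the filter of 1 CPM in 3 libraries (adjusted p = 0.0536) or halved counts (adjusted p = 0.0506). 9 rose when adjusted over the list alone. Camera called the list up (adjusted p = 2.5e-06), not with an estimated correlation (adjusted p = 0.14).

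None of the listed genes of the S, G2 and M phases passed the main test. Of these 44 genes 0 passed edgeR's test, over all genes or adjusted over the list alone, while 12 were lower at an unadjusted p under 0.05, 4 by DESeq2 and 0 by limma-voom. Mki67 stood at 13.8 ± 4.9 CPM in control and 8.98 ± 0.63 CPM in prolactin (log2 change -0.62, adjusted p = 0.21), and Foxm1 at 3.37 ± 1.04 and 2.84 ± 0.27 CPM (adjusted p = 0.624). Camera called the list down (adjusted p = 8.7e-08), not with an estimated correlation (adjusted p = 0.515). Its level in control replicate 3 lay 0.46 above its mean over the libraries, and without that library its median log2 change of -0.25 became -0.06 (adjusted p = 0.0204). Among 20 regulators of the G1 phase, Myc was the 1 that rose, from 15.1 ± 0.5 to 22.8 ± 0.7 CPM (log2 change 0.59, SE 0.056, adjusted p = 0.0023, passing without each single library), also when adjusted over the list alone, and the list was not called (adjusted p = 0.61). Cyclin D2, Ccnd2, stood at 516.5 ± 38.8 and 537.9 ± 37.9 CPM (adjusted p = 0.787), and the menin gene Men1 at 55.9 ± 4.0 and 60.1 ± 1.2 CPM (adjusted p = 0.482). Myc was also the 1 of 20 polyamine and ribosome biogenesis genes that rose (2 adjusted over the list alone). That list was called up (adjusted p = 0.00799), not with an estimated correlation (adjusted p = 0.515), nor without control replicate 3 (adjusted p = 0.188) or prolactin replicate 1 (adjusted p = 0.0745).

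Of 25 interferon-stimulated genes, 0 passed edgeR's test (0 adjusted over the list alone, 9 lower at an unadjusted p under 0.05, 1 by DESeq2 and 0 by limma-voom), and 2 had positive changes. Ifit3b had a log2 change of -0.48 (adjusted p = 0.208) and Irf9 -0.24 (adjusted p = 0.225). Camera called the list down (adjusted p = 4.1e-06), not with an estimated correlation (adjusted p = 0.515). Its level was highest in control replicate 3, 0.33 above its mean over the libraries. The median log2 change of -0.25 became -0.12 without that library and -0.37 without control replicate 2. Of 22 NF-kB targets and chemokines 0 passed edgeR's test over all genes (2 higher and 1 lower at an unadjusted p under 0.05, 1 each by DESeq2 and 0 by limma-voom), 1 rose and 1 fell adjusted over the list alone, and the list was not called (adjusted p = 0.298) but was called up without control replicate 1 (adjusted p = 4.1e-06), and turned to down, not called, without prolactin replicate 1 (adjusted p = 0.608).

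Of 13 transcripts of the mitochondrial genome 1 fell, and 0 had a positive change: mt-Co2, a subunit of cytochrome c oxidase, fell from 144.8 ± 3.8 to 97.3 ± 8.4 CPM (log2 change -0.57, SE 0.068, edgeR adjusted p = 0.0082). It did not pass without prolactin replicate 2 (adjusted p = 0.0687). Adjusted over the list alone, 4 fell. The list's median log2 change was -0.23 (-0.15 without control replicate 2), and camera called it down (adjusted p = 2.5e-10), not with an estimated correlation (adjusted p = 0.238), and fry did not call it (adjusted p = 0.122). Among 23 glycolysis genes, the pyruvate dehydrogenase kinase gene Pdk1 was the 1 that fell (log2 change -0.43, SE 0.069, adjusted p = 0.032), losing the call without any 1 prolactin library (adjusted p from 0.116 to 0.177). 5 fell when adjusted over the list alone. Camera called glycolysis down (adjusted p = 1.2e-05), not with an estimated correlation (adjusted p = 0.455), and its median of -0.14 was -0.06 without control replicate 1 and -0.22 without control replicate 2. Pdk4, of the same kinase family, was the 1 of 27 fatty acid genes that rose (0.59, SE 0.085, adjusted p = 0.021), though not without control replicate 2 or any 1 prolactin library (adjusted p from 0.052 to 0.134). Adjusted over the list alone, 2 fatty acid genes rose and 3 fell, and the list was not called (adjusted p = 0.298). Nuclear genes of the respiratory chain had 0 of 33 past the threshold, 0 also adjusted over the list alone, at an unadjusted p under 0.05 and by DESeq2 or limma-voom (camera adjusted p = 0.105). They were called down without control replicate 3 (adjusted p = 3.0e-05) or prolactin replicate 1 (adjusted p = 0.0279). Of 23 sterol synthesis genes 0 passed edgeR's test, adjusted either way, 1 was lower at an unadjusted p under 0.05 and 0 passed by DESeq2 or limma-voom (camera adjusted p = 0.697).

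Few stress and survival genes passed the test. Ern1, a sensor of the unfolded protein response, was the 1 of 27 in its list that rose, from 317.5 ± 38.8 to 467.2 ± 14.2 CPM (log2 change 0.56, SE 0.087, edgeR adjusted p = 0.030), and the list was not called (adjusted p = 0.344; 1 rose and 1 fell adjusted over the list alone). Jun was the 1 of 27 immediate-early genes that rose (0.31, SE 0.051, adjusted p = 0.034). Ern1 and Jun passed only with all libraries or without control replicate 3 (adjusted p otherwise from 0.0612 to 0.233). Of 28 apoptosis and survival genes, Tnfrsf11b was the 1 that rose, and of 32 ATF4 and amino acid genes 0 passed edgeR's test (9 higher and 3 lower at an unadjusted p under 0.05, 6 higher and 1 lower by DESeq2, 0 by limma-voom); the transcription factor Ddit3 had a log2 change of -0.36 (adjusted p = 0.0501) and passed without control replicate 3 (adjusted p = 0.049). In all, 5 immediate-early and 3 apoptosis genes rose, and 6 ATF4 genes rose and 1 fell, when adjusted over the list alone. Camera called the immediate-early (adjusted p = 0.00666), apoptosis (adjusted p = 0.0316) and ATF4 (adjusted p = 0.00367) lists up. None was called with an estimated correlation (adjusted p = 0.238, 0.511 and 0.511) or without prolactin replicate 1 (adjusted p = 0.0528, 0.0531 and 0.0755), and apoptosis was not called without control replicate 3 either (adjusted p = 0.221).

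**Figure D4:**
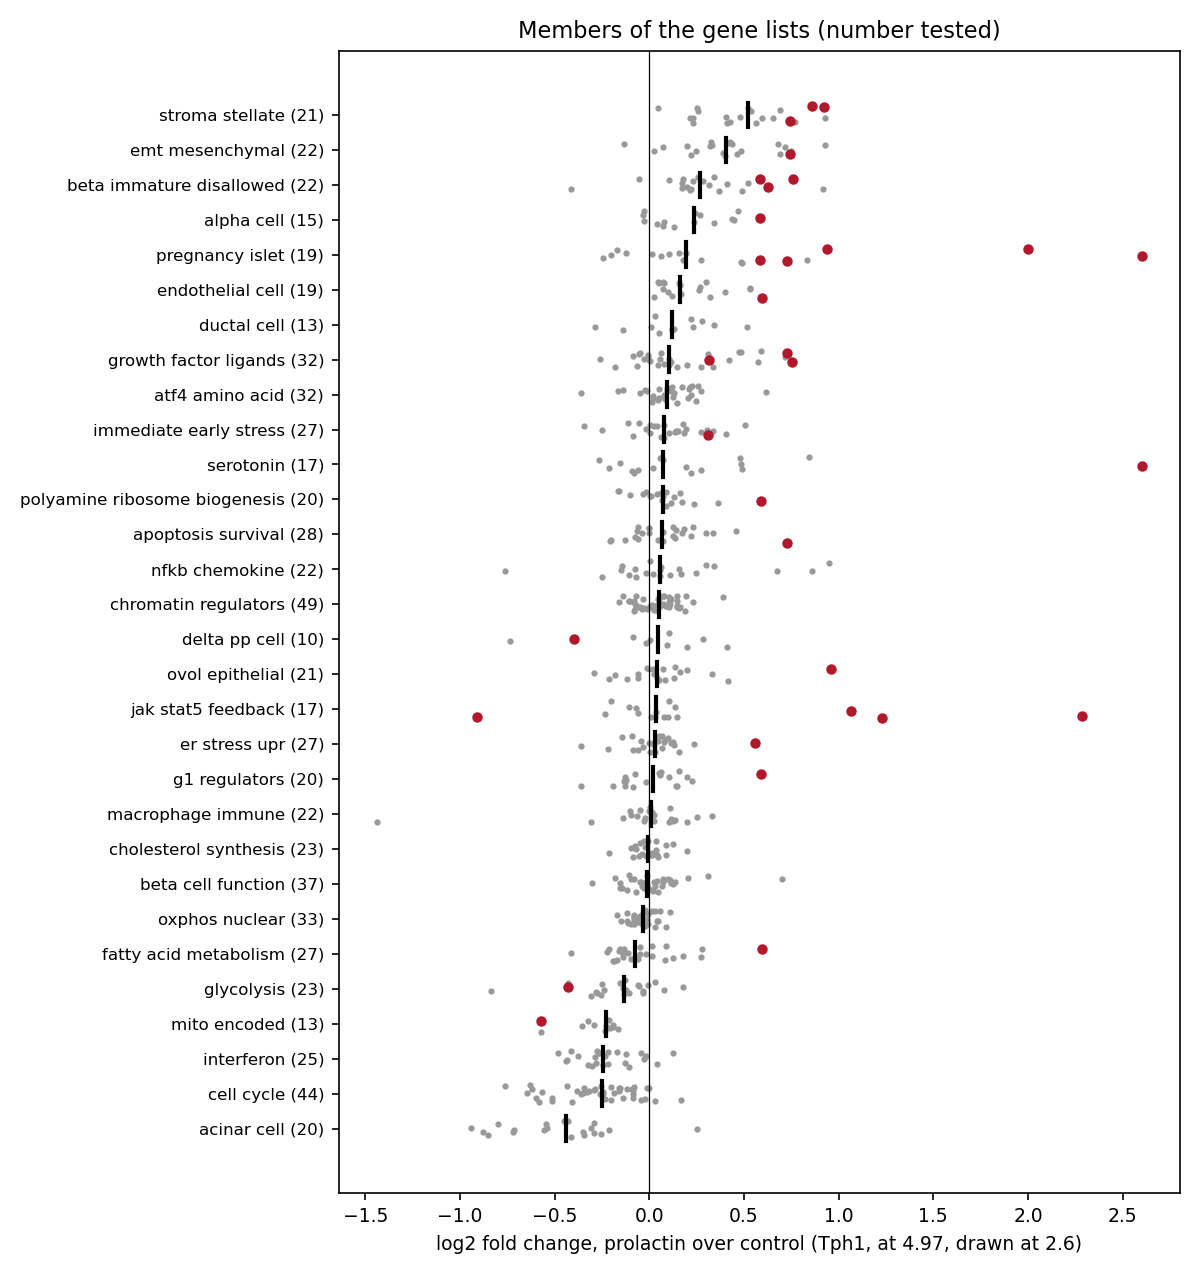
Log2 fold change of prolactin over control for the tested members of each of the 30 gene lists, with their number in brackets; red points passed the test over all genes, grey points did not, and black bars are medians. Medians run from -0.44 for acinar markers to 0.52 for stromal markers, and Tph1, at 4.97, is drawn at the right edge.

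Fewer genes fell, and by less. After Bcl6, the largest falls among named genes at 5 CPM or more were in the metallothioneins Mt2, from 501.2 ± 86.0 to 280.7 ± 29.9 CPM (log2 change -0.84, SE 0.13, edgeR adjusted p = 0.028), and Mt1, from 765.1 ± 126.1 to 458.8 ± 53.9 CPM (log2 change -0.74, SE 0.13, adjusted p = 0.045). Then came mt-Co2, Qpct, Tcf19, Tmem255a, the ubiquitin ligase gene Trim21, the aminopeptidase gene Enpep and the lysosomal thiol reductase gene Ifi30, with log2 changes from -0.57 to -0.45. Tcf19 did not pass with upper-quartile scaling (adjusted p = 0.0542) or limma-voom (adjusted p = 0.06). Of these 10 genes, Bcl6 kept its call in each fit without 1 library. The other 9 lost theirs without prolactin replicate 2 (adjusted p from 0.0627 to 0.239), and 8 of them also without prolactin replicate 3, mt-Co2 being the exception.

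The number of genes past the threshold depended on single libraries. It was 63 higher and 10 lower without control replicate 2, 342 and 234 without control replicate 3, 86 and 8 without prolactin replicate 1, 39 and 1 without prolactin replicate 2, and 39 and 2 without prolactin replicate 3; without control replicate 1, 121 were higher and 15 lower. Prolactin replicates 2 and 3 were much closer to each other than any other replicate pair, with a chi-square per degree of freedom of 6.46 against 75.3 to 217. They differed by more than sampling noise, which does not show that they came from separate islets, and were kept as separate samples. Summed into 1 library, they left 42 genes higher and 2 lower, all 44 among the 181. Each changed gene said above to lose its call without 1 library also lost it with these summed, except mt-Co2. Among genes given above as not passing, Acta2, Ddit3, Dnmt3b, Irx1, Irx2, Neurog3, Ppy, St14, Ifit3b and Trpm5 passed with DESeq2 and with no low-count filter. Sox9 passed with DESeq2 and Mki67 with no low-count filter. The higher genes made up 86.2% of the 181, 59.4% without control replicate 3 and 71.9% of the calls of DESeq2 (776 higher and 303 lower, also the numbers in the authors' deposited table). Of the 181 genes, 178 are called in the same direction in that table.

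Of the 30 lists, camera with a preset correlation called 17, with 13 up and 4 down, while fry's directional test called 2, the pregnancy list (adjusted p = 0.00638) and the growth factor list (adjusted p = 0.0299).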

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

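The summing of prolactin replicates 2 and 3, the halved counts and the other edgeR setting were chosen after the results were seen. All 181 changed genes kept their direction in every alternative that tested them, the stricter filter testing 166 of them and the fit without hormone and mitochondrial genes 179. In each of these genes the libraries were separated by condition. Leaving out or summing libraries therefore had almost no room to turn a sign, and the kept directions are no separate support. Counts of higher and lower genes, 156 and 25 as reported, were 470 and 127 with no low-count filter, 776 and 303 with DESeq2, 48 and 1 in the test against a change of 1.2-fold, and 42 and 2 with prolactin replicates 2 and 3 summed. With at least 1 CPM in 3 libraries they were 179 and 46. Leaving out 1 library gave 39 to 342 higher and 1 to 234 lower. The highest counts, 342 and 234, came without control replicate 3, so the smaller number of samples cannot account for that fit. That library lay furthest from the others (median distance 0.496 in log2 CPM, against 0.412 to 0.447). The cause was not tested. Size factors, upper-quartile scaling, limma-voom, the hormone and mitochondrial genes, halved counts and the other edgeR setting kept both counts within 1.5 times. Of the 181 genes, 38 passed in each fit without 1 library and with the replicates summed. The simulated false share was higher for DESeq2 than for edgeR.

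Whether replicate numbers pair the samples was not settled. Deviations from the condition means correlated by 0.205, 0.121 and -0.0279 between libraries numbered 1, 2 and 3. Those numbered 1 and those numbered 2 correlated best with each other, and those numbered 3 did not. With 3 libraries per condition these values cannot decide it. With the replicate block, 464 genes were higher and 134 lower, and 19 lists were called, the ductal (adjusted p = 0.0281) and NF-kB (adjusted p = 0.0281) lists in addition. Acta2, Ddit3, Dnmt3b, Irx1, Neurog3, Ppy, Tph2 and Trpm5 gained a call in that fit.

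Of the 30 lists, 17 were called, 1 with an estimated correlation and 2 by fry, and 17 to 19 when 1 library was left out. Some uncalled lists turned direction in those fits: acinar, beta-cell, sterol, chromatin, ductal, unfolded protein, G1, macrophage, NF-kB and respiratory; only the acinar list was called in the turned direction. Of 2361 values of the 140 named genes under alternatives, 2099 kept direction and side of the threshold, 120 lost the call, 134 gained it and 8 reversed. None of the 8 was in a changed gene, where separated libraries left almost no room for a reversal. Reversals came when 1 library was left out, over which Ins1 ranged from -0.147 to 0.0349, Foxm1 from -0.372 to 0.0366, Ccnd2 from -0.000588 to 0.114, Amy2b from -1.42 to 0.214, Pnliprp2 from -1.33 to 0.191 and Rbpjl from -1.81 to 0.0183 (log2 changes). Ins1 turned without control replicate 2 (0.0211), control replicate 3 (0.0349) or prolactin replicate 2 (0.00403), Ccnd2 without control replicate 1, and the others without control replicate 3. The cause was not tested. With halved counts, 21621 genes passed the filter, so depth decides whether the lowest genes are tested.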

Other observations

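The tests of gene families, of the stromal rise, of the closeness of prolactin replicates 2 and 3 and of loci without a gene name were chosen only after the results were seen; the count over splits of the samples was planned. Families were taken from the letters at the start of gene symbols, and the smallest family size, 5 at first, was lowered to 3 after the results were seen.

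Among families of genes with a shared symbol, collagen genes were the most enriched among those higher in prolactin: 8 of 45 tested rose (one-sided Fisher's exact test, p = 2.3e-09, adjusted p = 3.0e-06 over 1304 families, or 1.4e-06 over the 581 with at least 5 members). The test takes genes as independent, while members of a family can move together, so its p-values do not measure the spread between libraries. They were Col1a1 and Col1a2, both in the stromal list, Col4a1, Col4a2, Col15a1, Col19a1, Col22a1 and Col27a1. Stromal and endothelial markers also had positive changes (median log2 change 0.52 and 0.16), and the level of the stromal list in control replicate 3 lay 0.68 below its mean over the libraries. Col15a1 (log2 change 0.64, SE 0.051, edgeR adjusted p = 0.00078) kept its call without each single library, as did the basement-membrane proteoglycan gene Hspg2 (0.59, SE 0.055, adjusted p = 0.0018). So did Col19a1 and Col22a1. The other 5 collagen genes, Col1a1, Col1a2, Col4a1 (0.34), Col4a2 (0.34) and Col27a1, kept theirs in 1 of 6 such fits each and lost it with prolactin replicates 2 and 3 summed. Flavin monooxygenases were the other family past the threshold, with Fmo1, Fmo2 and Fmo4 higher among 4 tested (adjusted p = 0.00131), a family that enters only with the lowered size. Fmo4, Fmo1 and Fmo2 all lie between 162793188 and 162898726 on the minus strand of chromosome 1. They may therefore not be independent, as the test takes them to be. Fmo1 kept its call in each fit without 1 library, Fmo2 in 4 of 6 and Fmo4 in 3 of 6, and the latter pair lost it with the replicates summed. The metalloproteinase genes Adamts1, Adamts4 and Adamts5, the latent TGF-beta binding protein genes Ltbp2 and Ltbp4 and the thrombospondin genes Thbs1 and Thbs3 rose, but their families did not pass (adjusted p = 0.0824 for each). The same held for the dynein heavy chain genes Dnah8, Dnah9 and Dnah11 (adjusted p = 0.0824).

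Several single genes outside the lists also changed. Gfra3, a receptor for the neurotrophic factor artemin, rose from 10.8 ± 1.4 to 20.8 ± 1.2 CPM (log2 change 0.94, adjusted p = 0.0033), the carbonic anhydrase-related gene Car8 by 0.74 (adjusted p = 0.0029) and the transcriptional co-regulator gene Cited2 by 0.65 (adjusted p = 0.00063), each kept without any single library. Fev, a transcription factor of serotonin neurons that islet endocrine progenitors also express, rose by 0.52 (SE 0.070, adjusted p = 0.015) and kept its call in 3 of 6 such fits.

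Of 21 stromal markers 3 rose and 18 did not pass, and the list, called up by camera with the preset correlation, was not called with an estimated correlation (adjusted p = 0.238) or by fry (adjusted p = 0.135). One hypothesis for its positive changes is a larger share of stromal cells in the prolactin libraries. The list of stromal markers, of which 5 of 21 stand in another list and 21 reach 1 CPM in the control islets, has Sparc (197.4 ± 31.0 CPM in control and 265.2 ± 23.9 CPM in prolactin) and Col1a1 (186.5 ± 38.1 and 338.6 ± 39.5 CPM) as abundant members. Its median log2 change was 0.52 with all libraries and 0.30 without control replicate 3. Within it, 8 markers of cell identity had a median log2 change of 0.462 and 13 matrix genes 0.538, a difference of 0.0761 (permutation test, p = 0.636). The 8 were Pdgfra, Pdgfrb, Acta2, Tagln, Rgs5, Cspg4, Des and Thy1. A response of stromal cells that raised both kinds of gene would give the same, so this test cannot tell it from a larger share. A larger share of stromal cells stays open and may account for the positive changes. A smaller share of endocrine cells that raises the markers of all other cell types alike is argued against. Macrophage markers did not rise with the stromal ones (difference of medians -0.512, permutation p = 1.0e-05, the smallest that 100000 permutations can give). Over the fits without 1 library the macrophage median ran from -0.05 to 0.04, and the stromal one was at least 0.30. Both permutation tests shuffled genes, which move together here, so their p-values do not measure the spread between libraries. A smaller endocrine share that changes cell types unequally was not tested. Islet hormone genes held 15.9%, 16.9% and 15.7% of the counts in control replicates 1, 2 and 3, and 15.8%, 15.8% and 16% in the prolactin ones. These shares also depend on the hormone transcripts per cell, so they do not decide it. A trend with exon length is argued against, because its removal left the stromal median at 0.518 (SE 0.068). The fitted trend ran only from -0.0192 to 0.131 in log2 change. That SE is over genes, which move together here, and does not measure the spread between libraries. A response of stromal cells to prolactin, which the design names, was not tested separately and stays open.

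Prolactin replicates 2 and 3 were closer than other replicate pairs. The same counts deposited under both names are argued against by their totals, 230833584 and 264885071. Genes with over 100000 reads in the pair had a mean chi-square of 106, and those with 10000 to 100000 reads 5.71. A single library sequenced in separate runs could also differ by more than sampling noise, so these values cannot exclude it. In genes with 300 to 1000 reads the mean chi-square was 2.88, against 7.43 to 18.6 in the other within-condition pairs. Libraries from a single RNA or pool of islets could give that. The bounds of these tests were set after the values were seen, and the labels do not say how the islets were pooled. No biological explanation was tested.

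Of the 181 changed genes 23 have no gene name, 22 of them higher. A candidate explanation is reads or transcription from a neighbouring changed gene: 6 of the 23 (26.1%) lay within 20 kb of a changed named gene that moved the same way, against 51 of 7197 (0.709%) unchanged loci (Fisher's exact test, p = 1.7e-08). These were Gm17040 beside Cish, 5730420D15Rik beside Socs2, 1700108N11Rik beside Ovol2, Gm13522 beside Neb, Gm37583 beside Lactbl1 and Gm16308 beside Col22a1. The other 17 had no such neighbour, among them Gm38070, at a mean of 894 CPM with a log2 change of 0.78. Gm17040, 1700108N11Rik, Gm13522 and Gm16308 overlap their neighbour on the opposite strand, where counting without strand cannot part the reads. 5730420D15Rik and Gm37583 do not overlap theirs, and whether their reads come from the neighbour's transcript or a separate one is open.

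Of the 10 splits of the 6 libraries into equal groups, 1 gave as many changed genes as the real one, the real split itself with 181; the highest of the others gave 15 (control replicates 1 and 3 with prolactin replicate 1 against the rest). The splits are too few for a share under 0.05. Those that parted the close pair of prolactin replicates 2 and 3 gave 0 each, and had little room for calls. Besides the real split, those that kept the pair together gave 3, 15 and 0.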
